A study of Homo sapiens with 6 samples.

How the data were processed

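RNA-seq was performed on 6 libraries of SK-LMS-1 leiomyosarcoma spheroids, 3 at 0 mmHg and 3 at 7.2 mmHg. Per the labels' protocols, total RNA was isolated with the mirVana kit and libraries were made with the NEBNext Ultra II Directional kit, which keeps strand. STAR, Salmon and the build hg19 are named per the submitters' processing notes, with no role, version or annotation given in the sources used here. One table of gene symbols with a column per library was used, and every column was matched to a sample by the column name in its labels. No coordinates are given, because the reference at hand was of another build.

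The deposited values are whole numbers but were treated as a score, a scaled measure of expression, not as raw counts. In each library the median ratio of the values to the gene-wise geometric mean was between 1.002 and 1.005, while library totals ran from 14521451 to 14990967. Low values showed gaps and excesses that differed by library, such as 361 genes at a value of 3 and 644 at 4 in compression replicate 3 against 787 and 513 in control replicate 1. Raw counts do not behave in this way, whereas counts divided by size factors and rounded do, although no label records that step. A test for raw counts, planned before the data were examined, was therefore replaced by limma, and sequencing depth and intervals that need it are not given. A change of total RNA per cell would have been removed by such scaling.

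From the deposited values, log2(value + 1) was computed for the 14833 of 38552 genes with a value of at least 10 in at least 3 libraries, which held 99.9% of the summed values. Compressed and control libraries were compared with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, 2-sided, no covariate), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes, and the SE is that of the moderated fit. With 3 against 3 libraries an exact permutation test of a single gene cannot go below p = 0.1, so the limma p-values rest on the model. Lists with at least 5 tested members were compared with the other genes by camera at a preset inter-gene correlation of 0.01, with adjustment over 40 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera rests on the few residual degrees of freedom of 6 libraries. A list not called that way is therefore not shown to be unchanged.

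The 43 gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. Named genes were the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM, computed on the deposited totals, of at least 2 and no overlap between the groups, up to 4 called members with the smallest p of each list (or 2 members where none was called), and CYR61, CTGF, ANKRD1, PIEZO1, ACTA2, CNN1, MKI67, CDKN1A, VEGFA and COL1A1. Genes with no symbol were left out, and LOC identifiers were counted as such, which passed over 4 of them among the rises. The rule named 156 genes, some of which, with 1 of the lists, are not reported here. Older symbols were used where the table has them.

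Data were simulated over 14833 genes with the control means, the library totals and a smoothed trend of spread averaged over both groups. The same steps recovered 22% of genes changed 1.2-fold, 86% of those changed 1.5-fold and 100% of those changed 2-fold or 3-fold. Each size had 50 genes. Of 166 calls 7.23% were false, above the 5% aimed at. Both simulated groups had the same spread. The real median SD was 0.0965 among controls and 0.150 among compressed libraries, so these rates may differ for the real data. In a second simulation without changed genes, camera gave 2.55% of 2000 random lists of 22 genes a p under 0.05. Genes were drawn independently there. This rate therefore does not cover lists whose members vary together, such as ribosomal protein genes (estimated correlation 0.914) or mitosis genes (0.786). Alternatives were other scalings, filters, limma-voom, a replicate block, a stricter threshold and leaving out each library, with the same genes tested when a library was left out. Pseudocounts of 0.5 and 5, quantile and cyclic loess normalization, library weights, a robust variance prior and the joint removal of control replicate 3 and compression replicate 3 were added after seeing the data.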

Results

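RNA was sequenced from spheroids of SK-LMS-1, an established human leiomyosarcoma line, a malignancy of smooth muscle lineage. The 6 libraries fall into 2 groups of 3, uncompressed control spheroids (0 mmHg) and spheroids held under a compressive pressure of 7.2 mmHg. The question put to the comparison was which genes respond to compressive force. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Deposited values summed to between 14521451 and 14990967 per library. Because they appear to have been rescaled between libraries already, the sequencing depth behind them is unknown. Pairs of control libraries differed by a chi-square of 2.86 to 4.50 per gene and pairs of compressed libraries by 13.5 to 19.4, so no pair resembled a single library deposited again. The median SD of a gene on the log2 scale was 0.0965 among controls and 0.150 among compressed libraries. On the first principal component, which held 44.4% of the variance, the controls lay between -29.1 and -20.1, and compression replicates 1, 2 and 3 at 11.4, 17.2 and 41.3.

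In compressed spheroids 22 of 25 tested hypoxia-response genes and 9 of 20 glycolysis genes rose, while 18 of 25 mitosis, 10 of 27 DNA replication, 14 of 30 fibrillar and basement membrane matrix and 7 of 26 interferon-response genes fell. Camera called these 6 lists at its preset correlation and none of them with an estimated correlation (adjusted p = 0.333 to 0.64). The heme-degrading enzyme gene HMOX1 rose from 323 ± 24.2 to 3054 ± 1475 (SD, n = 3), 8.80-fold. The iron-binding protein gene LTF fell from 230.3 ± 14.2 to 34.7 ± 14.6, 6.83-fold lower. Without control replicates 1, 2 and 3 in turn, 17, 18 and 16 hypoxia and 4, 7 and 4 glycolysis genes rose, and 5, 5 and 2 mitosis, 1, 1 and 0 DNA replication, 9, 5 and 5 matrix and 3, 4 and 3 interferon genes fell. Without compression replicate 3, 10 mitosis and 4 DNA replication genes fell, and without compression replicate 1, 12 interferon genes fell. With no filter on low values 11 mitosis and 6 DNA replication genes fell. Camera called the 6 lists with each library left out. Of 14833 genes tested, 1480 changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 747 of them higher and 733 lower. At least 2-fold changes were made by 218 of these, 100 higher and 118 lower. The count of changed genes moved strongly when 1 library was left out, in fits that also had fewer libraries. It was 546, 533 and 371 without control replicates 1, 2 and 3, and 2902 and 862 without compression replicates 1 and 3. With no filter on low values it was 915, and with library quality weights, chosen after seeing the data, 2388. The count of at least 2-fold changes was 139, 137 and 87 without control replicates 1, 2 and 3, and 362 and 97 without compression replicates 1 and 3. Over the 1480 genes, compression replicates 1, 2 and 3 showed 0.891, 0.905 and 1.204 times the mean change. Leaving out control replicate 3 and compression replicate 3 together, a choice made after seeing the data, left 223 changed genes, 216 of them shared with the 1480 and in the same direction. Of the 6 lists it left 13 hypoxia and 4 glycolysis genes higher, and 1 mitosis, 0 DNA replication, 4 matrix and 1 interferon gene lower.

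**Figure D1:**
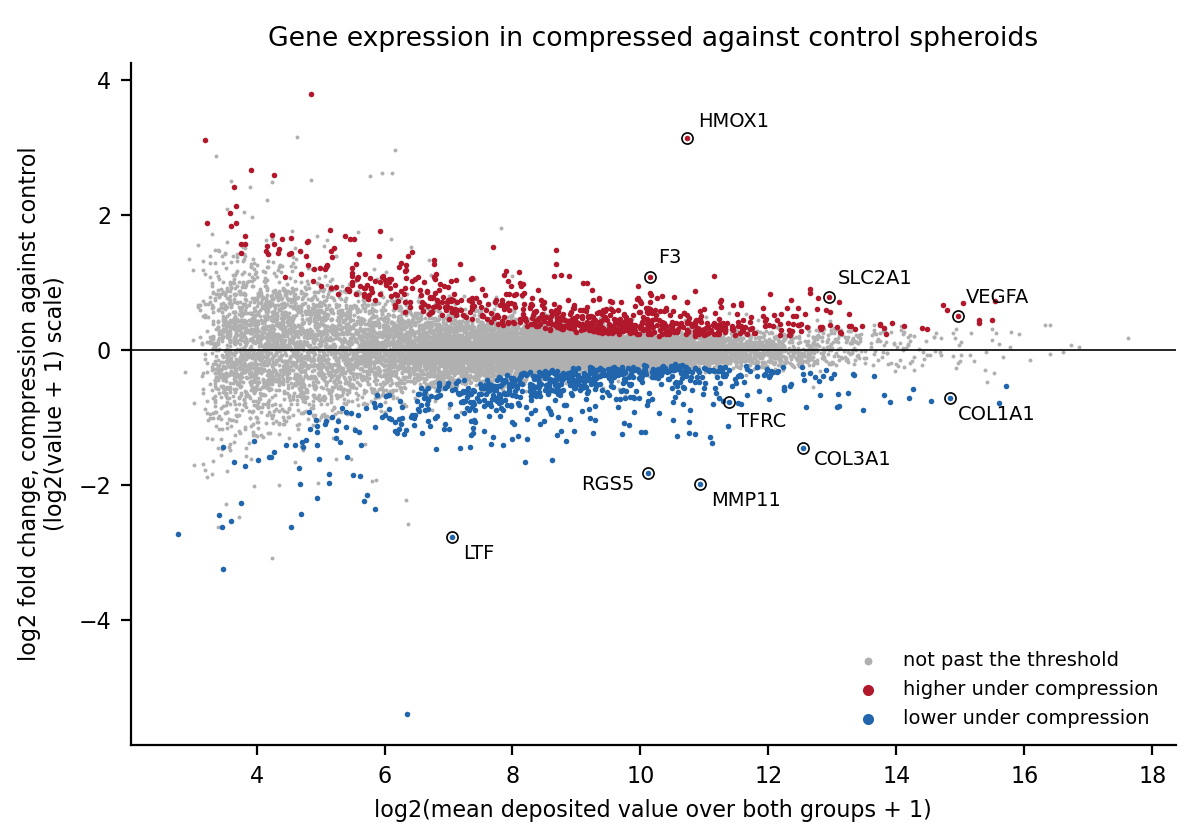
Each point is 1 of 14833 tested genes, with the log2 of its mean deposited value over both groups on the horizontal axis and its log2 fold change between compressed and control spheroids on the vertical axis. Red points (747) were higher and blue points (733) lower at an adjusted p under 0.05, grey points did not pass, and circled genes are named in the text, HMOX1 at 3.14 and LTF at -2.77.

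Among the 12 largest rises under the naming rule, HMOX1 had a log2 fold change of 3.14 ± 0.24 (SE, limma adjusted p = 0.000219). The others rose by 2.21-fold to 2.88-fold. HIF3A, a hypoxia-inducible factor family member, rose from 168 ± 19.3 to 381 ± 99.3 (limma adjusted p = 0.00371). The long noncoding RNA MIAT rose from 211 ± 57.6 to 605 ± 232, and LINC01004 from 43 ± 6.25 to 119 ± 48.05. NPIPB5 rose from 107 ± 39.8 to 304 ± 81.2. GABRE, a GABA-A receptor subunit gene, rose from 229 ± 47.9 to 588 ± 263 but was not called without control replicate 2 or 3 (adjusted p up to 0.0847). GSDMB, REC8 and SEPT5-GP1BB were not called without control replicate 2 or 3 or compression replicate 2 or 3 (adjusted p up to 0.112, 0.115 and 0.164). ZNF169 was not called without control replicate 1 or 2 or compression replicate 3 (adjusted p up to 0.093), and GDNF-AS1 with any 1 library but compression replicate 1 left out (adjusted p up to 0.0818). With a robust variance prior, chosen after seeing the data, MIAT, GSDMB, SEPT5-GP1BB and GABRE were not called (adjusted p = 0.0648, 0.0704, 0.0622 and 0.104), nor were GSDMB, SEPT5-GP1BB and REC8 with no filter on low values (adjusted p = 0.0598, 0.0795 and 0.0623) or SEPT5-GP1BB with library quality weights, also chosen after seeing the data (adjusted p = 0.0756). SLC25A25-AS1 rose by 1.25 on the log2 scale. The values of NPIPB5, a member of a family of near-identical copies, of the readthrough locus SEPT5-GP1BB and of the antisense loci GDNF-AS1 and SLC25A25-AS1 are uncertain, since the handling of shared reads and strand in counting is not given in the sources used here.

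The 12 largest falls ran from 2.60-fold to 6.83-fold, and each of these genes passed the test with any 1 library left out. LTF had a log2 fold change of -2.77 ± 0.25 (SE; limma adjusted p = 0.000409). MMP11, a matrix metalloproteinase gene, fell from 3076 ± 29.1 to 846 ± 392, and RGS5, a regulator of G-protein signalling, from 1732 ± 200.1 to 492 ± 94.6. MMP11 was not called with a robust variance prior, chosen after seeing the data (adjusted p = 0.063). COL3A1, which encodes a fibrillar collagen chain, fell from 8618 ± 508 to 3293 ± 1252, and the microfibril-associated gene MFAP4 from 291 ± 15.9 to 113 ± 32.01. KCNK2, which encodes the mechanically gated potassium channel TREK-1, fell from 335 ± 11.02 to 128 ± 25.1 (limma adjusted p = 0.000664). SCN1A, a voltage-gated sodium channel gene, fell from 234 ± 5.20 to 87.7 ± 23.8. METTL7A, TMEM119, ACKR4 and CNTN5 had log2 fold changes of -1.66, -1.62, -1.47 and -1.46. SPANXA1 fell from 3210.3 ± 435 to 1254 ± 305, a value left uncertain by its near-identical copies.

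Of the 25 tested hypoxia-response genes, 22 rose and 3 did not pass (25 higher adjusted over the list alone), with a median log2 fold change of 0.55. SLC2A1, the glucose transporter GLUT1, rose from 5819 ± 483 to 9984 ± 1088, ANGPTL4, a secreted lipoprotein lipase inhibitor, from 5178 ± 299.6 to 8863 ± 811, PFKFB3, a regulator of glycolytic flux, from 3049.7 ± 179 to 4660.3 ± 30.04, and the transcriptional repressor gene BHLHE40 from 3912 ± 192 to 6530.3 ± 273. VEGFA rose from 26349 ± 1008 to 37401 ± 5609.7 (limma adjusted p = 0.0196). VEGFA was not called with any 1 control library left out (adjusted p up to 0.117) or with quantile normalization, chosen after seeing the data (adjusted p = 0.0869). The list was called upward (camera adjusted p = 1.46e-23; adjusted p = 0.333 with an estimated correlation). Of 20 glycolysis genes, 9 rose (14 higher adjusted over the list alone; camera adjusted p = 6.14e-08; adjusted p = 0.333 with an estimated correlation). PDK1, which restrains pyruvate entry into mitochondria, rose from 767 ± 103 to 1268 ± 98.1, the hexokinase gene HK2 from 2160 ± 148 to 3448 ± 496, ENO2 from 2974 ± 248 to 5344 ± 1118 and PFKP from 4439.7 ± 350.0 to 6291 ± 459. Nuclear-encoded oxidative phosphorylation genes were called downward by a small median of -0.11, with 2 of 27 falling (4 lower adjusted over the list alone; camera adjusted p = 0.00297; adjusted p = 0.665 with an estimated correlation). The list was not called with control replicate 3 and compression replicate 3 left out together (camera adjusted p = 0.166). It held 0 falls with any 1 control library or compression replicate 2 left out and 8 without compression replicate 1. It held 4 falls when scaled to library totals or with a stricter filter, 1 with no filter and 6 with library quality weights, chosen after seeing the data. The genes that fell were NDUFA4 and SDHA, with log2 fold changes of -0.30 and -0.24. NDUFA4 was not called with any 1 control library or compression replicate 2 left out, nor SDHA with any 1 library but compression replicate 1 left out (adjusted p up to 0.0929 and 0.146), and SDHA was not called with no filter on low values (adjusted p = 0.0653).

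In the NRF2 oxidative stress list, 4 of 20 genes rose (7 higher and 1 lower adjusted over the list alone). Besides HMOX1 these were GCLM, a subunit of the enzyme that limits glutathione synthesis, from 521 ± 21.03 to 762 ± 91, the NADPH-producing malic enzyme ME1, from 338 ± 32.7 to 499.7 ± 32.3, and thioredoxin reductase TXNRD1, from 3336 ± 62.1 to 4613 ± 734, which was not called with any 1 control library left out (adjusted p up to 0.0745). The list was called (camera adjusted p = 0.00545; adjusted p = 0.399 with an estimated correlation). It was not called without compression replicate 1 (adjusted p = 0.0671). Genes of the integrated stress response rose in 5 of 21 cases (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00023; adjusted p = 0.532 with an estimated correlation). This list held 2, 2 and 2 rises without control replicates 1, 2 and 3, 8 without compression replicate 1 and 3 without compression replicate 3. It held 3 rises with no filter on low values, and 7 rises and 1 fall with library quality weights, chosen after seeing the data. VLDLR rose from 1077 ± 18.5 to 1630 ± 217 and the amino acid transporter gene SLC7A5 from 762 ± 4.04 to 1013 ± 25.7. CEBPG and PPP1R15A rose by 0.32 and 0.29 on the log2 scale. CEBPG was not called with any 1 control library left out and PPP1R15A was not called with any 1 library but compression replicate 1 left out (adjusted p up to 0.0906 and 0.14). PPP1R15A was also not called when scaled to library totals, with no filter on low values or with cyclic loess normalization, the last chosen after seeing the data (adjusted p = 0.0538, 0.0738 and 0.052). At the main settings, no call was made by limma or by limma-voom among 21 unfolded protein response genes (2 higher and 3 lower at an unadjusted p under 0.05; camera adjusted p = 0.803), where EDEM1 and CALR had log2 fold changes of 0.17 and -0.19, or among 20 heat shock genes (1 higher and 3 lower; camera adjusted p = 0.358), where DNAJB4 and HSPB8 had values of -0.29 and -0.86. Limma called 1 heat shock gene lower when scaled to library totals and 1 lower with a stricter filter, and without compression replicate 1 it called 3 heat shock genes lower and 1 unfolded protein response gene higher. With quantile or cyclic loess normalization, chosen after seeing the data, it called 1 unfolded protein response gene lower, and with library quality weights, also chosen then, it called 1 higher and 2 lower in that list and 2 lower among heat shock genes. The metallothionein list had too few tested members (4) for a list test. MT1X, a metal-binding protein gene, rose from 807 ± 93.95 to 1458 ± 297, and the other 3 did not pass. Of these, MT2A had the highest values, with means of 10559 in control and 10513 in compressed libraries. MT1E had means of 1259 and 1303, and MT3 of 29 and 42.3.

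**Figure D2:**
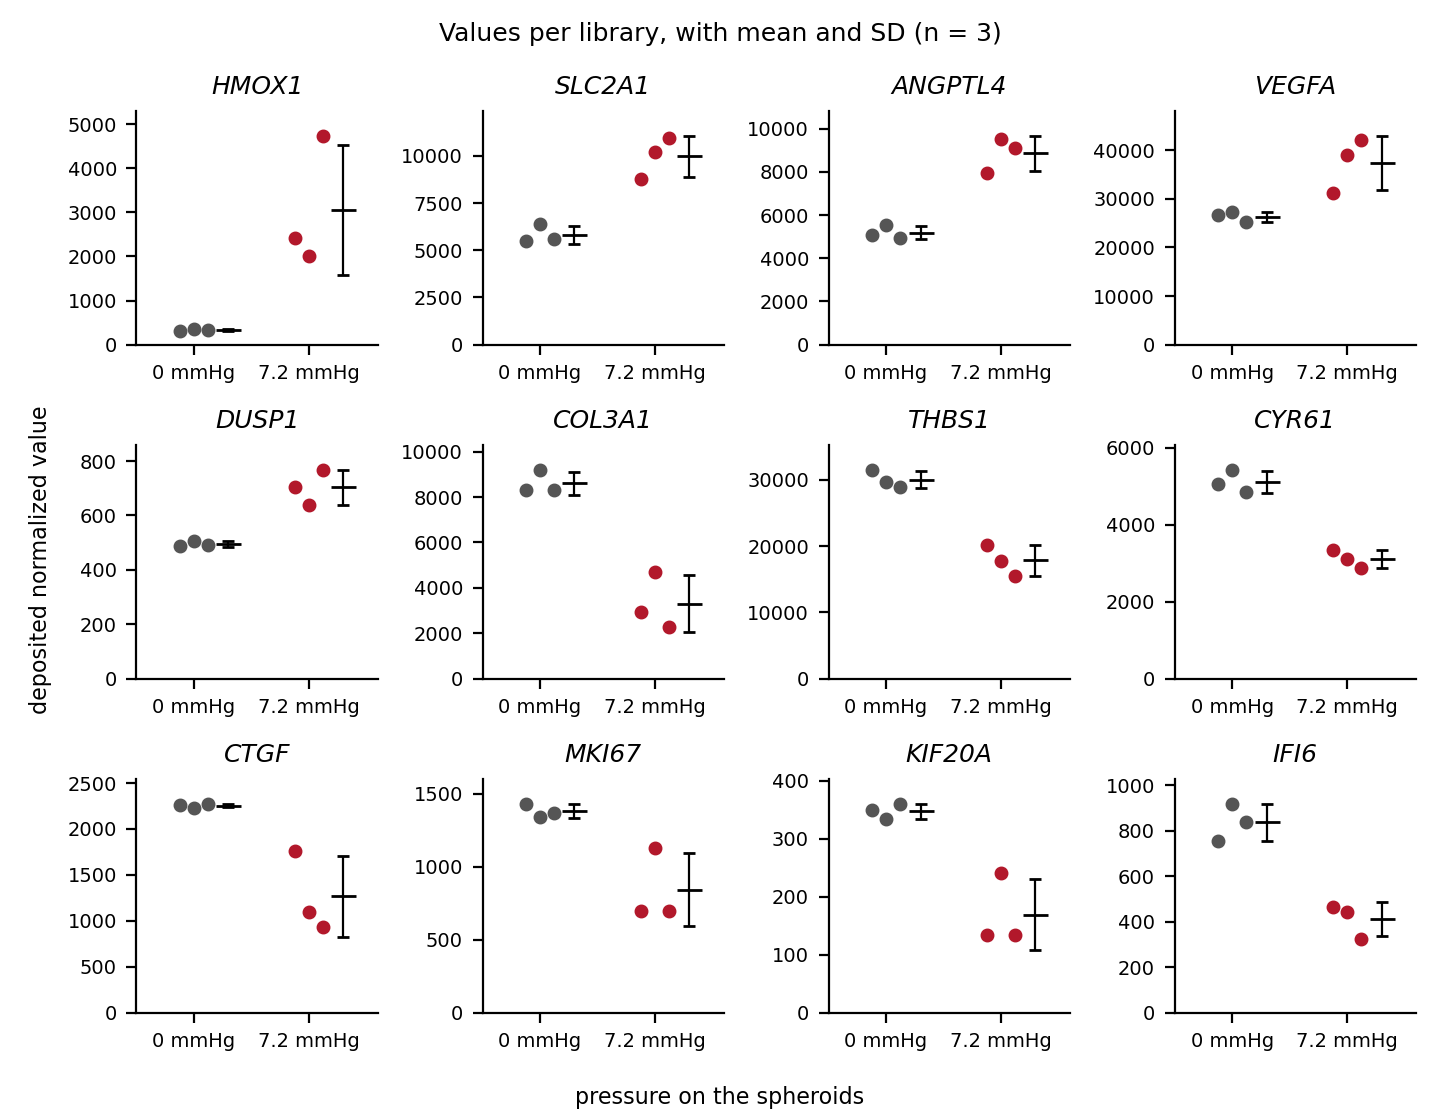
Points are the deposited values of 12 genes in each library at 0 mmHg (grey) and 7.2 mmHg (red), with each vertical axis starting at 0. The bar beside each group is its mean and SD (n = 3). The compressed HMOX1 values lie between 2008 and 4741 against 297 to 345 in the controls, and the groups of the 12 genes, which were picked among changed genes, do not overlap.

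Of 25 mitosis genes, 18 fell and 7 did not pass (23 lower adjusted over the list alone), with a median log2 fold change of -0.56 (camera adjusted p = 8.16e-14; adjusted p = 0.532 with an estimated correlation). CENPE, a kinetochore motor gene, fell from 262 ± 13.6 to 157 ± 6.93, and KIF20A, a cytokinesis motor gene, from 347 ± 13.1 to 169 ± 61.5. NUSAP1 fell from 468 ± 4.16 to 313 ± 53.2 and TPX2 from 1048 ± 46.6 to 699 ± 139.9. NUSAP1 was not called without control replicate 2 or 3 and TPX2 was not called without control replicate 1 or 3 (adjusted p up to 0.0567 and 0.053). The proliferation marker MKI67 fell from 1379 ± 47.2 to 842 ± 250.3 (limma adjusted p = 0.0127). DNA replication genes fell in 10 of 27 cases (18 lower adjusted over the list alone; camera adjusted p = 3.28e-08; adjusted p = 0.532 with an estimated correlation). PCNA, the replication clamp, fell from 1498 ± 43 to 1066 ± 173, and CDC45 from 120 ± 7.94 to 64.7 ± 16.2. The helicase subunit genes MCM6 and MCM3 fell by 0.44 and 0.35 on the log2 scale. MKI67, PCNA, CDC45 and MCM3 were not called with any 1 control library left out (adjusted p up to 0.0618, 0.0712, 0.0853 and 0.115), nor MCM6 without control replicate 2 or 3 (adjusted p up to 0.0622). Replication-dependent histone genes fell in 3 of 7 cases (6 lower adjusted over the list alone; camera adjusted p = 0.000825; adjusted p = 0.333 with an estimated correlation), and 2, 1 and 1 fell without control replicates 1, 2 and 3. The 3 were HIST1H2BK, from 469 ± 33.9 to 222 ± 40.1, HIST1H1C, from 260.3 ± 17.9 to 136 ± 41.2, and HIST1H2AC, from 102 ± 15.4 to 46.3 ± 17.9, whose values are uncertain because histone genes have near-identical copies. HIST1H1C was not called without control replicate 2 or 3, nor HIST1H2AC with any 1 control library left out (adjusted p up to 0.0736 and 0.075). Among 21 p53 targets, 3 rose and 3 fell (3 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.57), against 1 higher and 4 lower when scaled to library totals. The death receptor gene FAS fell from 321 ± 28.6 to 217 ± 4.04, and TP53I3 fell by 0.50 on the log2 scale. TNFRSF10B rose from 1672 ± 72.6 to 2033 ± 49.2. The cell-cycle inhibitor gene CDKN1A rose from 2212 ± 76.4 to 2591 ± 92.6 (limma adjusted p = 0.0392). FAS was not called without control replicate 3, TNFRSF10B with any 1 control library left out, TP53I3 with any 1 control library or compression replicate 3 left out, and CDKN1A with any 1 control library or compression replicate 2 left out (adjusted p up to 0.0568, 0.101, 0.102 and 0.175). CDKN1A was also not called when scaled to library totals, nor CDKN1A and MCL1 with no filter on low values (adjusted p = 0.0511, 0.0733 and 0.067). Of 20 apoptosis regulators, BMF, a pro-apoptotic BCL2-family gene, fell from 2433 ± 171 to 1642 ± 187, and the survival gene MCL1 rose by 0.25 on the log2 scale, though it was not called with any 1 library but compression replicate 1 left out (adjusted p up to 0.136; 3 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.372). Scaled to library totals, the apoptosis list had 1 higher and 2 lower.

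Of 30 fibrillar and basement membrane matrix genes, 14 fell and 1 rose (1 higher and 17 lower adjusted over the list alone; camera adjusted p = 1.62e-07; adjusted p = 0.64 with an estimated correlation). Besides COL3A1, the matricellular gene THBS1 fell from 30064 ± 1346 to 17859 ± 2339.7, SPARC from 23322 ± 1182 to 14449 ± 2908 and POSTN from 84.7 ± 10.8 to 19.3 ± 8.02. COL1A1 fell from 35961 ± 2968 to 22460.3 ± 6110.4 (limma adjusted p = 0.017). It was not called with any 1 control library left out (adjusted p up to 0.086). Collagen-processing genes fell in 4 of 20 cases and rose in 1 (2 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.062). LOXL4, a lysyl oxidase family gene, fell from 503 ± 12.3 to 268 ± 31.2, the transglutaminase gene TGM2 from 3333 ± 157 to 2555 ± 48.2, and PCOLCE fell by 0.60 on the log2 scale. The collagen prolyl hydroxylase gene P4HA1 rose from 4990.3 ± 178 to 6472 ± 294. PCOLCE was not called with any 1 control library left out (adjusted p up to 0.0817). Matrix proteolysis genes moved both ways, 5 higher and 8 lower of 28 (5 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.185). The plasminogen activator gene PLAT rose from 20969 ± 587 to 33386 ± 3547. The collagen-degrading cathepsin gene CTSK fell from 1828 ± 36.1 to 1133 ± 179. Fibroblast markers fell in 6 of 11 cases (7 lower adjusted over the list alone; camera adjusted p = 0.00199; adjusted p = 0.637 with an estimated correlation), among them THY1, from 1242 ± 73.5 to 766 ± 122, PDPN, from 1825 ± 63.4 to 1369 ± 136, and FAP, from 859 ± 52.6 to 625 ± 70.04. The number of fibroblast markers that fell was 3, 1 and 2 without control replicates 1, 2 and 3 and 3 without compression replicate 3. S100A13 fell by 0.39 on the log2 scale. PDPN was not called without control replicate 2, FAP without control replicate 2 or 3, and S100A13 with any 1 library but compression replicate 1 left out (adjusted p up to 0.0547, 0.0696 and 0.106).

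Integrin and focal adhesion genes moved both ways, 3 higher and 5 lower of 25 (6 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.515). The collagen-binding integrin gene ITGA11 fell from 554 ± 31.9 to 279 ± 45.2, ITGA1 from 988 ± 55.1 to 699 ± 7.21, the laminin-binding ITGA7 from 1001 ± 37.00 to 661 ± 78.7 and ITGB8 from 656 ± 27.9 to 452 ± 52.2. In the TGF-beta response list, 3 of 22 genes rose and 4 fell (4 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.314). LTBP2 fell from 3848 ± 159 to 2219.7 ± 326 and ID3 from 482 ± 12.9 to 267 ± 29.5. TGFBR2 fell by 0.33 and LRRC32 rose by 0.44 on the log2 scale. TGFBR2 was not called with any 1 control library left out and LRRC32 was not called without control replicate 3 (adjusted p up to 0.0934 and 0.051). Of 13 epithelial-mesenchymal factors, 2 fell and 1 rose (3 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.566), against 0 higher and 2 lower when scaled to library totals. The BMP antagonist gene GREM1 fell from 7949.7 ± 520.2 to 4411 ± 385, and PRRX1 fell by 0.33 on the log2 scale. ZEB2 rose by 0.28 on that scale. PRRX1 was not called with any 1 control library left out and ZEB2 was not called with any 1 library but compression replicate 1 left out (adjusted p up to 0.104 and 0.145). ZEB2 was also not called with no filter on low values or when scaled to library totals (adjusted p = 0.0617 and 0.0513). Cell-cell adhesion genes had 3 falls and 1 rise among 21 (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.372). CDH11 fell from 644 ± 24.03 to 438 ± 54.9, CLDN11 from 1813 ± 91.2 to 1314 ± 174 and JUP from 292 ± 22.5 to 179 ± 52.8, and CDH13 rose from 1161 ± 57.7 to 1503 ± 175. CLDN11 was not called without control replicate 3, nor JUP and CDH13 with any 1 library but compression replicate 1 left out (adjusted p up to 0.0695, 0.121 and 0.106).

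Among genes tied to mechanical signalling, responses were mixed. Of 22 YAP/TAZ-TEAD targets, 3 rose and 5 fell (4 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.277). The matricellular genes CYR61 (CCN1) and CTGF (CCN2) fell from 5115 ± 295 to 3107 ± 231 and from 2254 ± 20.4 to 1266 ± 438, with limma adjusted p of 0.000664 and 0.0108. CTGF was not called without control replicate 2 or 3 (adjusted p up to 0.0569) or with a robust variance prior, chosen after seeing the data (adjusted p = 0.0767). CCDC80 fell from 2024 ± 88.1 to 1532 ± 80.6. The coagulation initiator gene F3 rose from 723 ± 85.3 to 1544 ± 308. ANKRD1 stood at 13.3 ± 2.08 in control and 16.3 ± 10.4 in compressed libraries (limma adjusted p = 0.896). Immediate early genes rose in 6 of 21 cases (7 higher adjusted over the list alone; camera adjusted p = 5.26e-05; adjusted p = 0.333 with an estimated correlation). With any 1 control library left out 1 of them rose, and 10 rose without compression replicate 1. With library quality weights, chosen after seeing the data, 10 rose. The phosphatase gene DUSP1 rose from 496 ± 10.02 to 704 ± 64.00, the transcription factor genes FOS and JUN from 89.3 ± 3.21 to 148 ± 18.5 and from 2686 ± 61.1 to 3429 ± 277, and DUSP5 from 475 ± 22.7 to 678 ± 135. FOS, JUN and DUSP5 were not called with any 1 control library left out (adjusted p up to 0.0582, 0.0703 and 0.101). Among 13 mechanosensitive channel genes, KCNK2 and PKD2 fell. PKD2 fell by 0.30 on the log2 scale, though it was not called with any 1 control library or compression replicate 2 left out (adjusted p up to 0.103; 2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.598). PIEZO1, a pressure-gated cation channel gene, stood at 2993 ± 176 in control and 2844 ± 337 in compressed libraries (limma adjusted p = 0.592).

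Smooth muscle contractile genes included 1 rise and 1 fall among 14 (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.185), against 1 higher and 2 lower when scaled to library totals and 1 higher and 3 lower with quantile or cyclic loess normalization, the latter chosen after seeing the data. The myosin light chain kinase gene MYLK fell from 2976 ± 76.2 to 1832 ± 330.4, and SMTN rose from 2625 ± 209 to 3586 ± 403, though it was not called without control replicate 2 or 3 (adjusted p up to 0.0732). ACTA2, smooth muscle actin, had means of 114 ± 12.7 and 114 ± 8.14, and CNN1, calponin, 45.3 ± 8.08 and 55 ± 7 in control and compressed libraries (limma adjusted p = 0.992 and 0.433). Of 22 actin cytoskeleton genes, 1 rose and 1 fell (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.962), against 1 higher and 2 lower under each of those 3 scalings. FHL2 fell by 0.27 on the log2 scale. It was not called with any 1 library but compression replicate 1 left out (adjusted p up to 0.137) or with no filter on low values (adjusted p = 0.0501). The median of the actin cytoskeleton list was 0.0085 while its mean, -0.0021, and test were downward. DIAPH3, a formin gene, fell from 192 ± 9.17 to 118 ± 12.5. At the main settings, neither limma nor limma-voom called any of 18 nuclear envelope genes (2 higher and 6 lower at an unadjusted p under 0.05; 2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.313), where LEMD2 and SUN2 had log2 fold changes of 0.26 and 0.20. Limma called 1 higher and 0 lower of the nuclear envelope genes with median-of-ratios factors recomputed, 0 higher and 1 lower when scaled to library totals, 2 higher and 0 lower with a stricter filter, 3 higher and 4 lower without compression replicate 1 and 0 higher and 2 lower without compression replicate 2. The alternatives chosen after seeing the data called 0 to 2 higher and 0 to 1 lower.

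Interferon-response genes fell in 7 of 26 cases (15 lower adjusted over the list alone), with a median log2 fold change of -0.50 (camera adjusted p = 4.43e-07; adjusted p = 0.333 with an estimated correlation). With library quality weights, chosen after seeing the data, 11 of them fell. IFI6 fell from 837 ± 81 to 411 ± 75.2, and the interferon-induced genes IFIT2 and IFIT3 from 293 ± 22.7 to 151 ± 37.9 and from 458 ± 35.6 to 293 ± 32.97. Antigen presentation genes were called downward with 1 of 15 passing, B2M, from 11460.3 ± 364 to 8974 ± 636, which was not called with any 1 control library left out (adjusted p up to 0.0877; 2 lower adjusted over the list alone; camera adjusted p = 0.00399; adjusted p = 0.64 with an estimated correlation). With any 1 control library left out 0 antigen presentation genes fell, and 4 fell without compression replicate 1. The number was 2 when scaled to library totals, with a stricter filter or with limma-voom, and 2 to 3 under the alternatives chosen after seeing the data other than a pseudocount of 0.5 and the removal of control replicate 3 and compression replicate 3 together, which gave 1 and 0. NF-kB and cytokine genes went both ways, 6 higher and 6 lower of 29 (9 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.803), against 3 higher and 6 lower when scaled to library totals. The list's median of 0.04 differed in sign from its mean of -0.14. The chemokine genes CXCL6, CCL2 and CCL7 fell from 1241 ± 82.9 to 575 ± 85.1, from 2418 ± 229.8 to 1056 ± 285 and from 83 ± 5.57 to 17.7 ± 6.66, and the adhesion receptor gene VCAM1 from 596 ± 46.6 to 266 ± 72.5. Among 23 angiogenic and growth factor genes, 4 rose and 4 fell (5 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.803). BMP4 fell from 576 ± 11.02 to 249.7 ± 78.5 and BDNF from 640 ± 36.8 to 425 ± 56.4. AREG and BMP2 rose from 269.7 ± 17.8 to 449 ± 109 and from 366 ± 17.04 to 483 ± 33.6. AREG was not called without control replicate 2 or 3 and BMP2 was not called with any 1 control library left out (adjusted p up to 0.0792 and 0.0854).

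**Figure D3:**
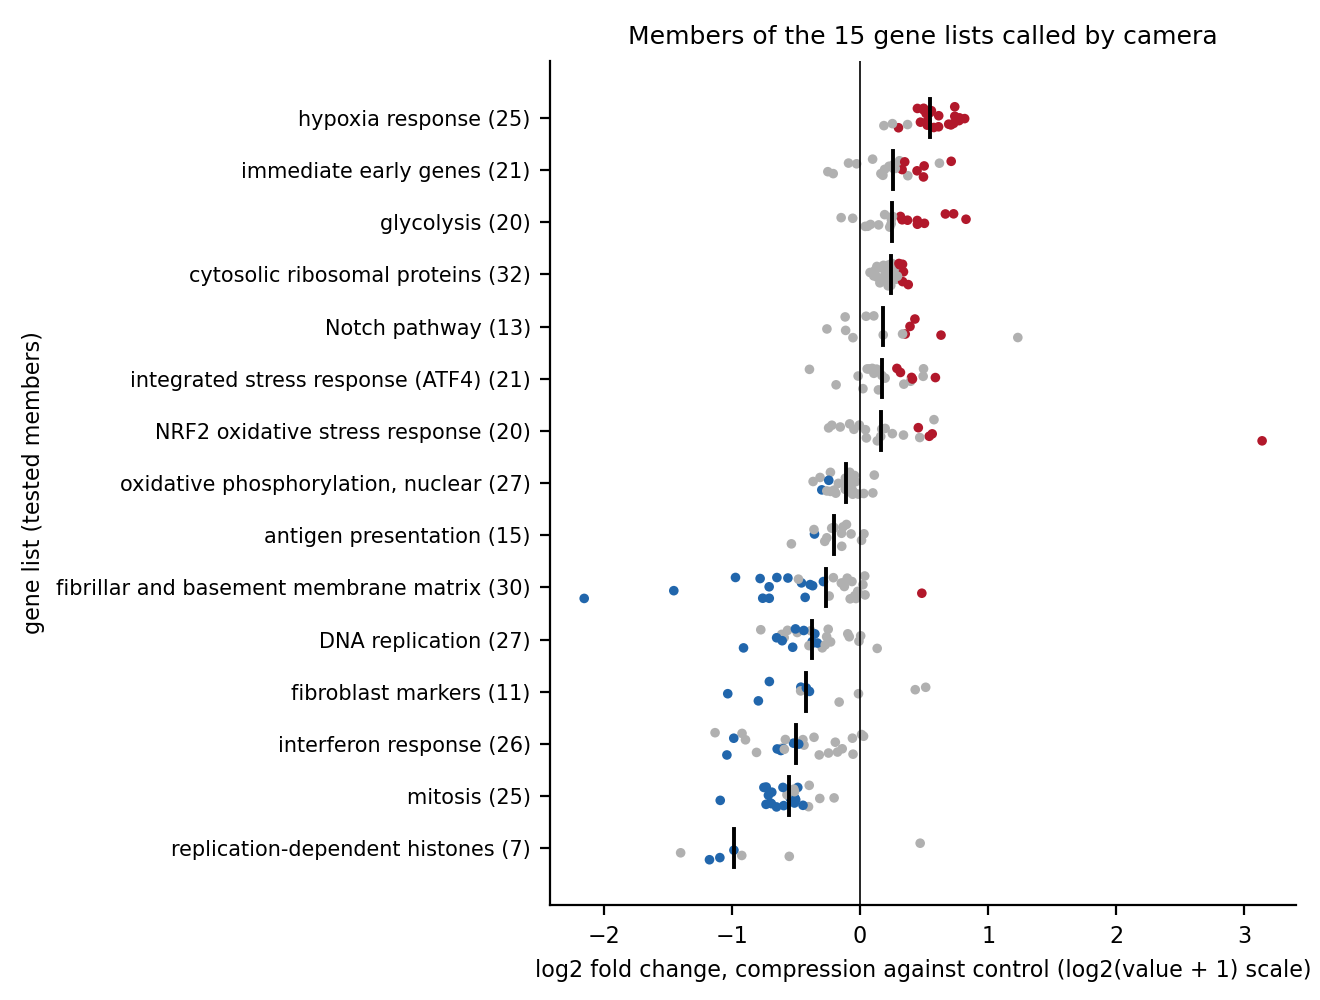
Each point is the log2 fold change of a tested gene in 1 of the 15 lists that camera called, with the number of tested genes in brackets, and the black bar is the list's median. Coloured points passed the limma test (red higher, blue lower) and grey points did not, with medians from -0.98 for replication-dependent histones to 0.55 for the hypoxia response.

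Cytosolic ribosomal protein genes rose in 7 of 32 cases (24 higher adjusted over the list alone), with a median log2 fold change of 0.24 (camera adjusted p = 5.55e-11; adjusted p = 0.64 with an estimated correlation). With any 1 control library left out 0 of them rose, and 18 and 12 rose without compression replicates 1 and 2. With no filter on low values 2 rose, and with quantile or cyclic loess normalization, chosen after seeing the data, 4. With library quality weights, also chosen then, 14 rose. RPS3 rose from 11949 ± 291 to 15578 ± 1803, and RPSA and RPS19 by 0.30 and 0.33 on the log2 scale, and none of these 3 was called with any 1 control library left out (adjusted p up to 0.1, 0.111 and 0.128). RPS19 was also not called with no filter on low values (adjusted p = 0.0588). Their values are uncertain where processed pseudogenes share reads. Notch pathway genes rose in 4 of 13 cases (5 higher adjusted over the list alone; camera adjusted p = 0.0354; adjusted p = 0.392 with an estimated correlation). The list was not called without control replicate 1, compression replicate 1 or compression replicate 2 (adjusted p = 0.0749, 0.0544 and 0.0522). It held 2, 0 and 0 rises without control replicates 1, 2 and 3 and 1 without compression replicate 3, and 2 with no filter on low values. The ligand gene JAG1 rose from 1114 ± 51.4 to 1463 ± 138, the receptor gene NOTCH1 from 251 ± 20.2 to 337 ± 18.01, and the targets HES1 and HES4 by 0.35 and 0.63 on the log2 scale. JAG1 was not called without control replicate 2 or 3, NOTCH1 without control replicate 2 or 3 or compression replicate 3, HES1 with any 1 library but compression replicate 2 left out, and HES4 with any 1 library left out (adjusted p up to 0.0703, 0.108, 0.13 and 0.151). HES1 and HES4 were also not called with no filter on low values (adjusted p = 0.0591 and 0.0886), nor HES4 when scaled to library totals, with limma-voom or, chosen after seeing the data, with quantile or cyclic loess normalization (adjusted p = 0.0538, 0.0511, 0.057 and 0.0527). Of 22 Wnt pathway genes, 2 rose and 2 fell (2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.117), against 2 higher and 1 lower with quantile normalization. The receptor gene FZD8 rose from 942 ± 32.3 to 1642 ± 82.1 and the ligand gene WNT7B from 185 ± 7.21 to 296 ± 50.3. The co-receptor gene LRP5 fell from 2336 ± 32.5 to 1126 ± 196, and LGR4 fell by 0.42 on the log2 scale. WNT7B was not called without control replicate 2, nor LGR4 with any 1 library but compression replicate 1 left out (adjusted p up to 0.0543 and 0.189). LGR4 was also not called with no filter on low values or with quantile or cyclic loess normalization, the latter chosen after seeing the data (adjusted p = 0.0775, 0.0657 and 0.0578).

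Cholesterol synthesis genes moved both ways, 3 higher and 1 lower of 22 (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.598), against 3 higher and 0 lower with quantile or cyclic loess normalization. The median of the cholesterol list was -0.0059 and its mean 0.05. INSIG1 rose from 927 ± 63.3 to 1269 ± 23.6. SC5D rose by 0.26 and HMGCS1 fell by 0.27 on the log2 scale. SC5D was not called with any 1 library but compression replicate 2 left out, nor HMGCS1 with any 1 library but compression replicate 1 left out (adjusted p up to 0.171 and 0.186). SC5D was also not called when scaled to library totals or with no filter on low values (adjusted p = 0.0705 and 0.0841), nor HMGCS1 with no filter or, chosen after seeing the data, quantile or cyclic loess normalization (adjusted p = 0.0742, 0.0558 and 0.0577). Of 19 fatty acid and lipid storage genes, 2 rose, the desaturase gene SCD from 4035 ± 199 to 5246 ± 151 and the lipid droplet gene PLIN2 from 1577 ± 163 to 2045 ± 171. PLIN2 was not called without control replicate 1 or 3 or compression replicate 3 (adjusted p up to 0.115; 4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.185). Scaled to library totals, this list had 2 higher and 1 lower. Autophagy and lysosome genes included 2 rises and 3 falls among 24 (3 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0897). The lysosomal enzyme gene CTSA fell from 6120.3 ± 156 to 4343 ± 618. The autophagy kinase gene ULK1 and the cholesterol transporter gene NPC1 rose from 1358 ± 108 to 1762 ± 59.2 and from 1944 ± 39.6 to 2575 ± 355. CTSA was not called without control replicate 2 or 3, ULK1 without control replicate 3 and NPC1 with any 1 control library left out (adjusted p up to 0.0522, 0.0588 and 0.0843).

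Among epithelial, endothelial and leukocyte markers, MUC1 alone passed the test. Of 9 tested epithelial markers, MUC1 rose from 205 ± 41.00 to 316 ± 16.6, though it was not called without control replicate 3 or compression replicate 2 (adjusted p up to 0.0643; 3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.608). At the main settings, neither limma nor limma-voom called any of 9 endothelial markers (2 higher and 1 lower at an unadjusted p under 0.05; 1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.363), where ROBO4 and PECAM1 had log2 fold changes of 0.60 and -0.27. Limma called 1 endothelial marker lower when scaled to library totals or without compression replicate 1, and 1 higher with a stricter filter. Among the alternatives chosen after seeing the data, library quality weights gave 1 lower and a robust variance prior 1 higher. Only 2 of 16 leukocyte markers were high enough to test, CD68 and CD14, at -0.15 and -0.38 (limma adjusted p = 0.221 and 0.247), and the pan-leukocyte marker PTPRC had values of 0 to 2 in all 6 libraries. Among 24 housekeeping genes, the transferrin receptor gene TFRC fell from 3347 ± 35.2 to 1993 ± 416 and 23 did not pass (1 lower adjusted over the list alone; camera adjusted p = 0.0825). The mitochondrially encoded list could not be tested, since 0 of its 13 genes were listed in the table used here. Camera called 15 of 40 tested lists, 7 upward and 8 downward, and with an estimated correlation it called 0, with 5 at an unadjusted p under 0.05. That loss is not a matter of correlation alone. The histone list had an estimated correlation of 0.0106, near the preset 0.01, and the Notch list one of -0.0207, and both lost their call. Fry, which tests whether a list moves on balance, called 7, each also called by camera. It did not call the lists of mitosis and DNA replication genes (fry adjusted p = 0.0689 for each), matrix genes (0.17), ribosomal protein genes (0.119), the integrated stress response and fibroblast markers (0.0767 for each), oxidative phosphorylation (0.199) or antigen presentation (0.111). In the 25 lists that camera did not call, counting a gene once per list, 100 members passed, and 53, 50 and 40 without control replicates 1, 2 and 3 and 164 without compression replicate 1.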

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

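The tests with other pseudocounts, quantile and cyclic loess normalization, library weights, a robust prior and 2 libraries left out together were chosen after seeing the data. The 1480 changed genes (747 higher, 733 lower, 218 at least 2-fold) became 385 (164, 221 and 88) at an adjusted p under 0.01 and 915 (431 and 484) with no filter on low values, where 26062 genes were tested. Library quality weights gave 2388 (1219 and 1169). Leaving out control replicate 3 and compression replicate 3 together gave 223 (83, 140 and 48), with fewer samples. Leaving out 1 library gave 371 to 2902 changed genes, 167 to 1435 higher, 204 to 1467 lower and 87 to 362 at least 2-fold. The highest counts came without compression replicate 1 and the lowest without control replicate 3; the cause was not tested. The other alternatives gave 1171 to 1584 changed genes. Scaling to library totals moved the split to 624 higher and 869 lower. Every gene called in both the main test and an alternative had the same direction in both. Against 15 lists in the main test, camera called 14 to 19 under the alternatives that change the values, filter or libraries, with 15 to 17 when 1 library was left out. At the main settings camera with an estimated correlation called 0 and fry 7.

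The values showed no pairing of the libraries by replicate number. So few libraries cannot exclude a pairing, and the labels do not say whether a number marks a shared day or culture. Same-numbered deviations correlated at -0.0267, 0.0428 and -0.11, and no control library correlated best with its own number except replicate 2. The replicate block gave 1171 changed genes, 577 higher and 594 lower, and 15 lists, and 11 of the 156 named genes were not called with it (GSDMB, REC8, FHL2, ZEB2, SDHA, HMGCS1, SC5D, CDKN1A, LGR4, HES1 and HES4).

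Of the 156 named genes, 73 were called with each library left out in turn; without control replicates 1, 2 and 3, 46, 62 and 66 lost their call, and 87 lost it with control replicate 3 and compression replicate 3 left out together. Only uncalled genes changed sign. ACTA2 was at -0.0166 when scaled to library totals, -0.0445 with control replicate 3 and compression replicate 3 left out, and between -0.0685 and 0.0869 with 1 library left out. ANKRD1 was at -0.274 and PIEZO1 at 0.00381 with library quality weights, and ANKRD1 at -0.304 with that pair left out and between -0.342 and 0.50 with 1 library left out. The cause was not tested. DESeq2 was not run because the values do not behave as raw counts. Depth is unknown, so how far it limits low genes cannot be given.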

Other observations

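The level-matched test of loci with LOC, LINC or antisense names and the test of held-out complement genes were chosen before their results were seen. The other tests below were chosen only after the result was seen. The genes named here other than HMOX1 were picked after their values were seen. A fall of complement and acute-phase genes under compression was noticed while looking through the values. C3, the central complement component, fell from 14832 ± 411 to 8077 ± 1025 (SD, n = 3), CFB from 3991 ± 134 to 2531 ± 275, SAA1 from 3059 ± 269 to 1270 ± 305 and SAA2 from 1957 ± 122 to 959 ± 185 (limma adjusted p = 0.000664, 0.000891, 0.000875 and 0.000743; SAA1 and SAA2 are near-identical and uncertain). A shared fall of the class was then tested on 19 other tested members not looked at before. Of these 3 fell, C1R, C1S and LCN2, and 16 did not pass, with a median log2 fold change of -0.16 and a camera p of 0.0317 (p = 0.154 with an estimated correlation). C1S fell from 4451 ± 16.5 to 2934 ± 413. The near-identical pair C4A and C4B, whose values are uncertain, had log2 fold changes of 0.50 and -2.01 (limma adjusted p = 0.0547 and 0.185). The median of the 19 is consistent with a fall shared by part of the class, as a hypothesis.

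Over 127 gene families grouped by symbol, a scan added after seeing the data, the collagen genes (COL) held more falls than other genes, 11 of 34 (Fisher's exact test, adjusted p = 0.000102), and the lysine demethylase genes (KDM) more rises, 7 of 17 (adjusted p = 0.00127). Under each of the other 4 scalings 11 collagen genes fell and 6 or 7 KDM genes rose. Family counts with a library left out are not given here. The collagen falls include COL1A1, COL1A2, COL3A1, COL5A2, COL4A1, COL4A2 and COL11A1. These are also in the matrix list, so the scan is not independent of that list. Family members are not independent, so these p-values describe the lists. KDM6B rose from 1558 ± 149 to 2326 ± 158, KDM7A from 324 ± 7.55 to 477 ± 35.3, KDM4B from 1631 ± 66.1 to 2307 ± 219 and KDM3A from 1449.7 ± 48.05 to 2025 ± 300.1; KDM3A and KDM4B are also in the hypoxia list. HIF1A fell from 6908 ± 254 to 5092 ± 851 (limma adjusted p = 0.0187). RNA28S5, a ribosomal RNA locus with many copies and so uncertain, fell from 3145 ± 288 to 1857 ± 176.

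The real grouping gave 1480 changed genes and the highest of the other splits of the 6 libraries gave 1. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

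In the hypoxia list 22 of 25 genes rose and in the mitosis list 18 of 25 fell, with neither list called with an estimated correlation (adjusted p = 0.333 and 0.532) and only the first called by fry (adjusted p = 0.0196 and 0.0689). Removing a trend on GC content and transcript length left the medians at 0.55 (hypoxia) and -0.54 (mitosis), close to 0.55 and -0.56 before, which argues against that trend as the whole cause, although the trend removed was small (SD 0.0386). The medians were smallest at 0.51 without control replicate 1 (hypoxia) and -0.45 without compression replicate 3 (mitosis), which argues against a single library as the cause of the medians, although only 2 mitosis genes passed without control replicate 3. A response to pressure itself, to lower oxygen in compressed spheroids, or to slower growth may each underlie the pattern; no value here separates them, and the biological explanation was not tested beyond the groups.

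HMOX1 rose 8.80-fold, with 1475 SD among compressed libraries. Its highest adjusted p with 1 library left out was 0.00469, which argues against a single library. The rest of the NRF2 list, 19 genes, was also higher (camera p = 0.0119, and camera p = 0.12 with an estimated correlation), by a median of 0.16. A general rise of the list may therefore be part of the pattern. Whether it accounts for the size of the HMOX1 rise was not tested. NFE2L2, which encodes NRF2, and its antagonist BACH1 at the HMOX1 gene had log2 fold changes of -0.19 and 0.27 (limma adjusted p = 0.11 and 0.112). These are RNA levels, and the activity of NRF2, BACH1 or other regulators of HMOX1 was not tested.

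Loci with LOC, LINC or antisense names had a median log2 fold change of 0.16 over 1375 tested, against -0.01 over the other 13458. Under the other 4 scalings the median of these loci was 0.11 to 0.16. The share of rises did not differ past the threshold from that among other genes (5.82% against 4.96%; Fisher's exact test p = 0.174), but falls were fewer (1.31% against 5.31%; p = 6.31e-14), and camera p = 0.00219 became 0.15 with an estimated correlation. Other genes matched on mean level had a median of -0.0113 (95th percentile of 10000 draws 0.0127), which argues against low expression as the cause. Without control replicate 3 and compression replicate 3, 6 of these loci rose and 4 fell, against 80 and 18 with all libraries. Calls were lost over all genes too, with 83 higher and 140 lower against 747 and 733. This drop in counts is therefore not particular to these loci. The median of these loci without those 2 libraries was 0.0777, against 0.156 with all libraries, close to the bound set. A source in these 2 libraries and a shift in all libraries therefore cannot be told apart. A check of GC content was void, since 25.8% of the loci had a value.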
